A study of Mus musculus with 12 samples.

How the data were processed

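The values were the log2 signals of Affymetrix Mouse Gene 1.0 ST arrays as deposited by the authors. They came from RMA per the submitters' processing notes, which state neither version nor settings. The table had 35556 probe sets and 12 arrays, with values from 3.2 to 14.0, no identical pair of arrays and no column without a sample. The values were tested as deposited, without further normalization or filtering.

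Gene symbols came from the platform annotation. At least 1 symbol was given for 23410 probe sets, exactly 1 for 21789, several for 1621 and none for 12146. The gene identifiers of 21698 of the single-symbol probe sets were in the mouse RefSeq table (GRCm38.p6), and 0 symbols needed an update. That table served for symbols alone, and no genome coordinates are given. A gene was represented by its brightest single-symbol probe set, 999 of 19938 genes having more than 1.

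Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 12 arrays and the 4 groups of layer and treatment. Tests were two-sided, with 8 residual and 3.27 prior degrees of freedom. The p-values were adjusted by Benjamini-Hochberg over the 23410 probe sets with a symbol, separately in each comparison, and passed under 0.05. The comparisons, the gene lists, the rule for naming genes and the alternatives to each choice were fixed before the data were examined, apart from those named below. The p-values measure only the spread between these samples, since the labels do not say whether the 3 arrays of a group came from separate animals or cultures.

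Genes were named by rule. In each comparison these were the 12 with the smallest p in each direction among those past the threshold whose groups did not overlap, and up to 4 members of each gene list past the threshold. Fgf10, Bmp8a, Esr1, Pgr, Igf1 and Ltf were always named. Predicted gene models, microRNAs and olfactory receptors were counted but not named. The text gives a selection of the genes so named.

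The 32 gene lists, 6 of them cell type markers, were written from general knowledge. Each was tested with camera (limma) at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 32 lists of a comparison. Further tests used the correlation estimated in each list, fry, and 10000 random lists matched on mean value. Members were also counted after adjustment over the list alone. No list that passed in any of the 5 comparisons changed direction under another scaling of the arrays.

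Replicate numbers were taken from the sample titles, and the labels do not state which layers came from 1 co-culture. The residuals of arrays with the same number were compared. Epithelial and stromal vehicle arrays each correlated best with their own number (r = 0.17, 0.14 and 0.13), while vehicle and E2 arrays of the epithelial layer (-0.42, 0.27 and 0.27) and the stromal layer (0.20, -0.04 and 0.03) and the layers under E2 (-0.31, 0.23 and -0.06) did not all do so. The comparisons were not paired, although the vehicle arrays of the layers did match by number, and blocks for that number were run as alternatives.

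The alternatives were a filter on low values, all probe sets of the table, 3 further scalings, a variance trend with a robust prior, array weights, the mean of all probe sets of a gene, other thresholds, blocks for the replicate number, the arrays of 1 layer or treatment alone, and leaving out each array. Chosen after seeing the data were the averages of E2 replicates 1 and 2 and of other pairs of replicates, the epithelial marker mean as a covariate, a split of the epithelial arrays as a covariate, and the repeats of the list tests without each array.

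The procedure was tested on simulated data with 23410 probe sets and 50 changed at each fold. It recovered 44%, 92%, 98% and 98% of changes of 1.5, 2, 4 and 8-fold in the epithelial design and 44%, 86%, 96% and 98% in the stromal design. With 200 probe sets changed, 177 and 175 probe sets were called, 11 and 13 of them falsely. The simulated noise was independent, with 1 spread per probe set for all 12 arrays. The real groups spread unequally, with a median SD of 0.185 and 0.158 in epithelium and 0.0946 and 0.0804 in stroma. These rates therefore need not hold for the real arrays.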

Results

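The series profiled mouse uterine epithelial and stromal cells that had been grown together as a primary co-culture and then harvested as separate layers. Epithelial sheets sat on matrigel-coated inserts and stromal cells on cover slips, both from CD-1 uteri on day 4 of pseudopregnancy. After a night without hormones the co-cultures were treated for 2 days, either with estradiol (E2) at 10 nM or with ethanol alone at 0.01% (vehicle). There were 4 groups of 3 arrays, namely epithelial vehicle, epithelial E2, stromal vehicle and stromal E2, 12 arrays in all. Each array gave log2 values for 35556 probe sets, and the number of arrays per group limits the precision. Of these, 23410 with at least 1 gene symbol were tested, with array medians from 7.38 to 7.43. Over all probe sets of the table the medians differed by layer, from 7.01 to 7.14 in the epithelial and 6.92 to 6.95 in the stromal arrays. Below, values after ± are standard errors of a log2 difference from limma unless SD is written, n is 3 arrays per group, and an adjusted p is Benjamini-Hochberg adjusted over all probe sets tested. The standard errors and intervals use 1 spread per probe set shared by all 12 arrays, although the epithelial arrays spread more than the stromal ones. Folds are ratios of the deposited values. Whether a value lay above background was not tested, so a fold over a group far below the array medians is no measure of the ratio of transcripts.

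The first comparison asked what E2 changed in the epithelial layer. Akr1c14, a hydroxysteroid dehydrogenase, went from 5.52 ± 0.53 (SD, n = 3) under vehicle to 10.72 ± 0.18 (SD, n = 3) under E2, a log2 difference of 5.20 ± 0.30 (adjusted p = 1.29e-05). Pgr, the progesterone receptor, rose 7.89-fold (2.98 ± 0.24, adjusted p = 0.000138), from 7.59 ± 0.40 (SD) to 10.57 ± 0.40 (SD). Oxtr, the oxytocin receptor, rose 8.64-fold (3.11 ± 0.25), and Greb1, a cofactor of the estrogen receptor, rose 11.4-fold (3.51 ± 0.57, adjusted p = 0.00813). In the other direction the matrix-degrading gelatinase Mmp9 fell by 1.67 ± 0.18 on the log2 scale (3.17-fold, adjusted p = 0.00102), and Csf1, the macrophage growth factor, fell by 1.07 ± 0.10 (2.10-fold, adjusted p = 0.000378).

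Among the other genes with the smallest p-values, the metabolic enzymes Idh1 (isocitrate dehydrogenase) and Glul (glutamine synthetase) rose 3.69-fold and 3.49-fold. Ptgdr2, a prostaglandin D receptor, rose 5.41-fold, Socs2, an inhibitor of cytokine signalling, 2.98-fold, and the neurite protein Nrn1 by 3.00 ± 0.21 on the log2 scale. Kap (3.37-fold), Amtn (3.22-fold), Btbd3 (2.75-fold) and Tnfrsf19 (1.99-fold) rose as well. The fallers included the membrane protease Mmp14 (-0.81), the TGF-beta receptor Tgfbr1 (-0.94), the secretory kinase Fam20c (-0.83), the NF-kappaB inhibitor Nfkbie (-0.69) and the nonmuscle myosin Myh9 (-0.71). Mamdc2 (-1.79), Nuak2 (-1.21), Enc1 (-0.79), Apbb2 (-0.89) and Disp1 (-0.72) fell too. The adjusted p of these genes lay between 1.29e-05 and 0.00268, and in each of them all 3 E2 arrays stood on the same side of all 3 vehicle arrays. In total 415 probe sets rose and 263 fell, 678 of 23410, of which 171 and 64 changed at least 2-fold.

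Of the genes the study followed, Fgf10, a stromal growth factor for epithelia, measured 0.92 ± 0.40 higher with E2 in the epithelial layer (adjusted p = 0.286), and Bmp8a, a bone morphogenetic protein, 0.59 ± 0.20 higher (adjusted p = 0.153). Neither passed. The estrogen receptor gene Esr1 (0.25 ± 0.14, adjusted p = 0.456) and Ltf, the lactoferrin gene of estrogen-stimulated epithelium (-0.76 ± 0.43, adjusted p = 0.435), did not pass either. Igf1, an insulin-like growth factor, rose 2.24-fold (1.16 ± 0.20, adjusted p = 0.0105).

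**Figure D1:**
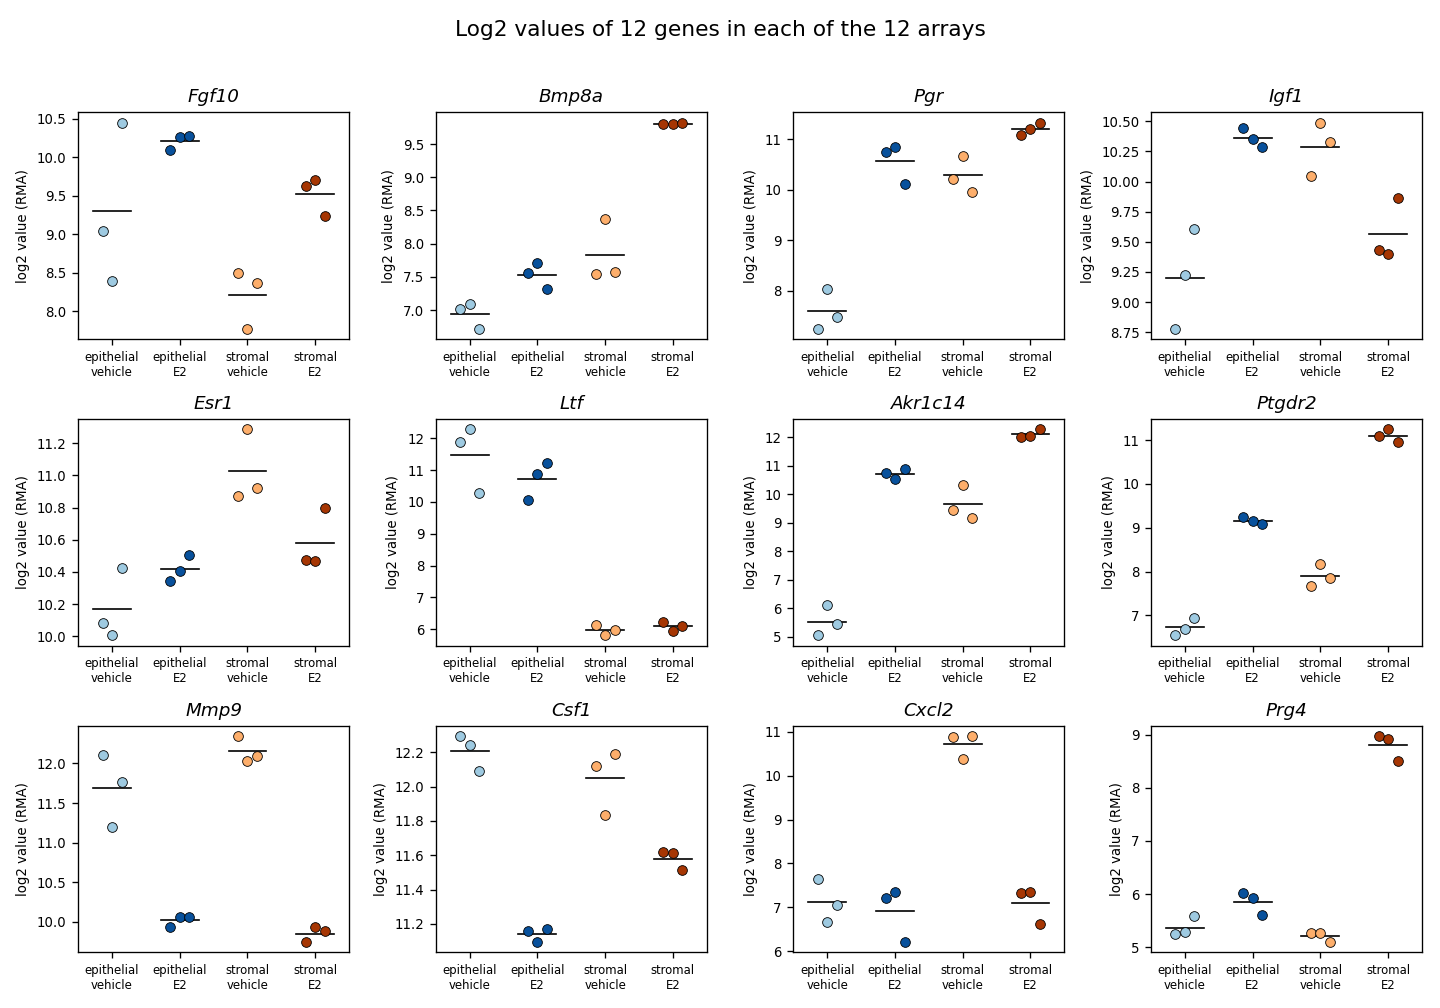
Log2 values (vertical axes) of 12 genes in each of the 12 arrays, grouped along the horizontal axis as epithelial vehicle, epithelial E2, stromal vehicle and stromal E2; points are arrays and lines are group means. Akr1c14 rises from 5.52 to 10.72 in the epithelial layer, and Bmp8a from 7.83 to 9.81 in the stromal layer.

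Gene lists fixed from general knowledge of uterine cells were compared with all other genes by camera, and 12 of 32 passed in the epithelial layer. With an estimated correlation between genes none passed, the lowest adjusted p being 0.117. The self-contained test fry called 3 of them, namely hypoxia and glycolysis (adjusted p = 0.0174), matrix proteases and inhibitors (0.0107) and p53 targets (0.0107). Hypoxia and glycolysis genes rose together, with 9 of 19 measured rising, 0 falling and 10 not passing (11 rising when adjusted over the list alone). Their median was 0.59 (adjusted p = 5.03e-10, and adjusted p = 0.297 with an estimated correlation), and 0.31 without vehicle replicate 2. Examples were the vasodilator peptide Adm (1.38 ± 0.19, 2.60-fold), the glycolytic enzymes Pgk1 (0.65 ± 0.11) and Tpi1 (0.59 ± 0.11) and the adenylate kinase Ak4 (1.00 ± 0.17). The mean of the list went from 10.35 to 10.95 in epithelium, against 10.97 under vehicle and 10.77 under E2 in stroma. A larger stromal share in the E2 epithelial arrays was not told apart from a response of epithelial cells. Of 30 measured uterine estrogen-responsive genes, 7 rose and 1 fell (11 and 5 adjusted over the list alone), led by Pgr, Greb1, Igf1 and the spindle checkpoint gene Mad2l1 (0.98 ± 0.14). Ccnd1, the cyclin of G1 in that list, fell by 1.66 ± 0.33 (adjusted p = 0.0214). The list median was 0.24 (adjusted p = 0.0239, and adjusted p = 0.493 with an estimated correlation), and the call was lost without vehicle replicate 1 (median 0.16, adjusted p = 0.161) or vehicle replicate 3 (adjusted p = 0.463). In the decidualization list the gap junction gene Gja1 alone rose (1.22 ± 0.14, adjusted p = 0.00114) among 18 measured, and 8 rose and 1 fell adjusted over the list alone. The median was 0.33 (adjusted p = 0.00501, and adjusted p = 0.457 with an estimated correlation), and without E2 replicate 2 the adjusted p was 0.0609. Without vehicle replicate 2 that median was 0.14, and without E2 replicate 3 it was 0.62.

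In the list of matrix proteases and inhibitors 3 of 22 fell, 0 rose and 19 did not pass (7 fell and 0 rose adjusted over the list alone), namely Mmp9, Mmp14 and the urokinase gene Plau (-0.94 ± 0.21). The median was -0.38 (adjusted p = 5.2e-06, and adjusted p = 0.117 with an estimated correlation), and -0.61 without vehicle replicate 2 and -0.23 without vehicle replicate 3. Inflammatory genes had 4 of 26 falling, 0 rising and 22 not passing (8 falling and 1 rising adjusted over the list alone), namely Csf1, the chemokine Cxcl5 (-1.96 ± 0.29), the colony-stimulating factor Csf2 (-2.02 ± 0.38) and the cytokine Tnf (-1.47 ± 0.31). Their median was -0.33 (adjusted p = 0.000157, and adjusted p = 0.457 with an estimated correlation). Interferon response genes had a median of -0.35 with 0 of 22 passing by limma (3 lower adjusted over the list alone, adjusted p = 1.62e-05, and adjusted p = 0.457 with an estimated correlation). The p53 targets, with 0 of 12 passing by limma over all genes or over the list alone, had a median of -0.28 (adjusted p = 0.00133, and adjusted p = 0.117 with an estimated correlation). In the unfolded protein response the protein disulfide isomerase Pdia6 alone fell (-0.45 ± 0.09) among 21 measured, 4 when adjusted over the list alone. The list had a median of -0.17 (adjusted p = 0.000404, and adjusted p = 0.465 with an estimated correlation), and it was -0.08 (adjusted p = 0.0739) without vehicle replicate 2 and -0.03 (adjusted p = 0.0615) without E2 replicate 3. Mitosis and G2/M genes had a median of 0.13 with 0 of 29 passing by limma over all genes or over the list alone (adjusted p = 0.0438, and adjusted p = 0.775 with an estimated correlation). That call was lost without vehicle replicate 1 (median 0.08, adjusted p = 0.271), vehicle replicate 3 (median 0.03, adjusted p = 0.568) or E2 replicate 1 (median 0.02, adjusted p = 0.506), and without vehicle replicate 2 the median was 0.23.

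Markers of cell types moved in the same arrays as these genes. Epithelial markers had a median of -0.68 (adjusted p = 5.59e-08, and adjusted p = 0.457 with an estimated correlation), 18 of 19 measuring lower with E2, although the claudin Cldn4 alone passed (-1.24 ± 0.25) and 5 were lower adjusted over the list alone. Their mean per array was 10.26, 10.89 and 9.26 under vehicle and 9.21, 9.40 and 9.48 under E2, against 6.78 to 7.25 in the stromal arrays. The list median was -0.35 without vehicle replicate 2 and -1.09 without vehicle replicate 3. Junction genes went with them, with a median of -0.42 (adjusted p = 0.000329, and adjusted p = 0.457 with an estimated correlation), Cldn1 (-2.04 ± 0.37) and the cadherin Cdh3 (-0.95 ± 0.18) falling and Gja1 rising among 23 (5 lower and 1 higher adjusted over the list alone). The junction call was lost without vehicle replicate 2 (median -0.16, adjusted p = 0.0983). Leukocyte markers had a median of 0.56 (adjusted p = 2.13e-05, and adjusted p = 0.457 with an estimated correlation), with the macrophage receptor Csf1r rising (1.01 ± 0.14) among 16 and 4 rising adjusted over the list alone. Their mean per array was 8.52, 8.20 and 8.55 under vehicle (8.42 ± 0.19, SD, n = 3) and 9.15, 9.22 and 8.44 under E2 (8.94 ± 0.43, SD, n = 3), E2 replicate 3 lying within the vehicle range. Stromal markers had a median of 0.17 with 0 of 20 passing by limma and 1 higher adjusted over the list alone (adjusted p = 0.202). Smooth muscle markers had a median of -0.13 (adjusted p = 0.144), with the smooth muscle actin Actg2 falling (-1.02 ± 0.21) among 11 and 1 higher and 4 lower adjusted over the list alone. Mesothelial markers had a median of -0.15 (adjusted p = 0.386), with Msln falling (-1.32 ± 0.19) among 6 and 1 higher and 1 lower adjusted over the list alone. Among 12 endothelial markers the VEGF receptor Kdr rose (1.33 ± 0.26), 1 being higher and 2 lower adjusted over the list alone.

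**Figure D2:**
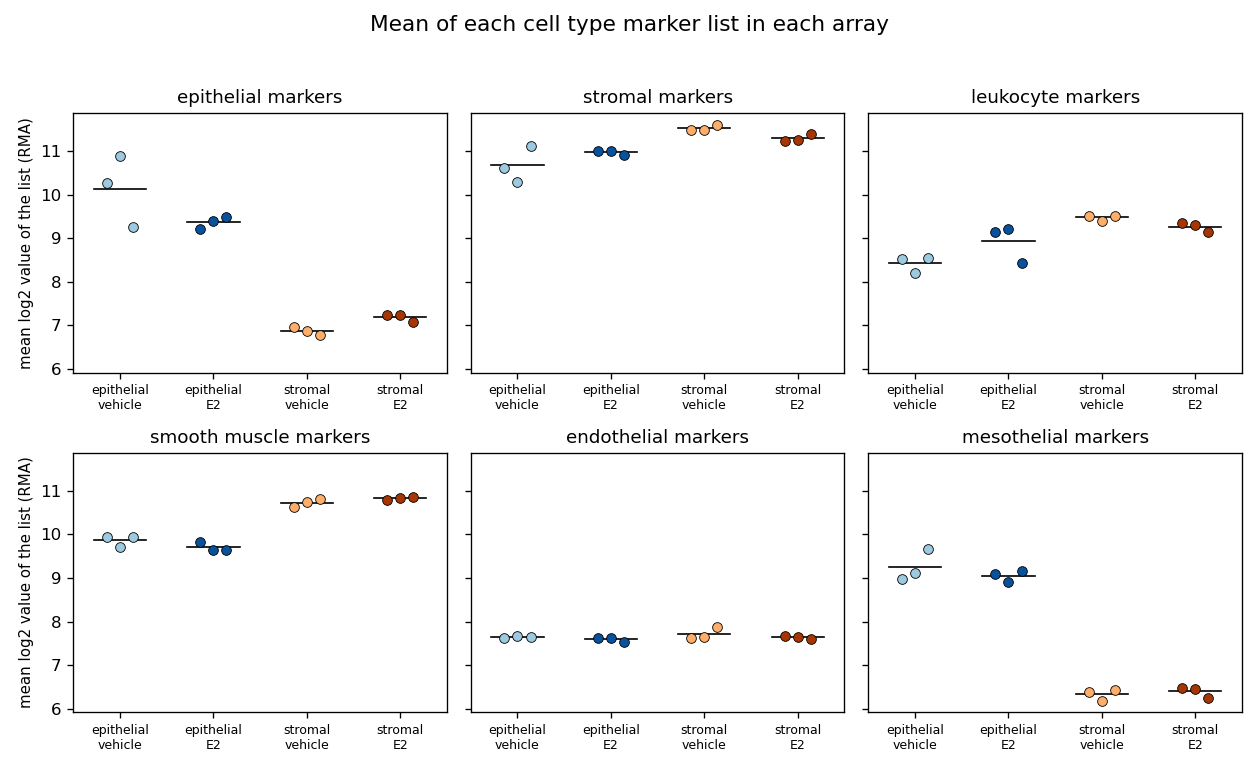
Mean log2 value of 6 lists of cell type markers (vertical axes) in each of the 12 arrays, grouped along the horizontal axis by layer and treatment; points are arrays and lines are group means. Epithelial markers span 9.26 to 10.89 in the vehicle epithelial arrays and 6.78 to 7.25 in the stromal arrays.

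Growth factor lists did not pass in the epithelial layer but held genes that did. In FGF signalling Fgf2 (1.17 ± 0.12, adjusted p = 0.000533) and Fgf9 (1.01 ± 0.22) rose among 23 (3 higher and 1 lower adjusted over the list alone). Bmp6 (0.94 ± 0.13) and the activin subunit Inhbb (1.03 ± 0.19) rose and the receptor Acvr1 (-0.51 ± 0.11) fell among 32 BMP and TGF-beta genes (6 and 3 adjusted over the list alone). The 4 WNT genes that passed among 36 rose, namely Dkk2 (1.94 ± 0.24), Sfrp4 (1.68 ± 0.26), Sfrp2 (2.21 ± 0.42) and Dkk3 (0.70 ± 0.15), with 5 higher and 5 lower adjusted over the list alone. Igfbp3, a binding protein of insulin-like growth factors, fell by 1.23 ± 0.20 while Igf1 rose, among 15 (2 and 1 adjusted over the list alone). Nrg1 (0.96 ± 0.17) and Errfi1 (0.72 ± 0.14) rose among 12 EGF family genes (2 and 1 adjusted over the list alone). Retinoid genes changed both ways among 16, with Aldh1a1, Aldh1a2 and Crabp2 rising by 1.25 ± 0.28, 1.17 ± 0.22 and 1.10 ± 0.20 and Aldh1a3 falling by 0.61 ± 0.14 (6 and 2 adjusted over the list alone). Stra6 of that list, named again below, passed as a faller too (-1.10 ± 0.26). Matrix genes had Thbs2 rising (0.92 ± 0.10) and Vcan (-1.53 ± 0.22), Col18a1 (-0.81 ± 0.15) and Col8a1 (-0.48 ± 0.11) falling among 24 (4 and 5 adjusted over the list alone).

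The remaining lists had few or no members past the threshold in the epithelial layer. In DNA replication and G1/S, 1 of 31 fell (Ccnd1), as did 1 adjusted over the list alone. Steroid receptors and cofactors had Pgr rising and the membrane receptor Gper1 falling (-0.90 ± 0.20) among 12, the same numbers as adjusted over the list alone. Krt14 fell (-0.72 ± 0.14) among 20 squamous genes, Aldh1a1 rose among 13 uterine gland genes, and Sgk1 (0.76 ± 0.17) rose and Kcnq1 (-1.38 ± 0.29) fell among 19 ion and water transport genes. Adjusted over the list alone these gave 0 higher and 1 lower, 1 and 2, and 1 and 1. Pgk1 alone passed among 9 reference genes, 1 adjusted over the list alone. Progesterone-responsive genes (17), heat shock genes (12) and cholesterol synthesis genes (17) had 0 members passing by limma, with 0 and 1, 1 and 1, and 0 and 0 higher and lower adjusted over the list alone.

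The spread between arrays was larger in the epithelial layer (median SD 0.185 under vehicle and 0.158 under E2) than in the stromal layer (0.0946 and 0.0804), and the 12-array fit of 678 calls gave 49 when fitted on the 6 epithelial arrays alone and 89 with E2 replicates 1 and 2 averaged. It gave 411, 1634, 219, 220 and 1513 without vehicle replicate 1, vehicle replicate 3, E2 replicate 1, E2 replicate 2 and E2 replicate 3. The balance of directions moved with them, with 46 higher and 3 lower on the 6 epithelial arrays, 724 and 910 without vehicle replicate 3, and 1179 and 334 without E2 replicate 3. Of the 69 named genes past the threshold, 37 kept their call in every fit that left out 1 array (Cldn4, Igf1, Kdr and Tnf not among them), 30 with the pair averaged and 16 on the epithelial arrays alone, where Greb1, Mmp9 and Mmp14 did not pass.

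The second comparison asked what E2 changed in the stromal layer. Bmp8a rose from 7.83 ± 0.47 (SD, n = 3) to 9.81 ± 0.01 (SD, n = 3), 3.94-fold (1.98 ± 0.20, adjusted p = 0.000284). Fgf10 measured 8.22 ± 0.39 (SD, n = 3) under vehicle and 9.52 ± 0.25 (SD, n = 3) under E2, a difference of 1.30 ± 0.40 that did not pass (adjusted p = 0.129). Prg4, the lubricin gene, rose by 3.59 ± 0.15 on the log2 scale (adjusted p = 9.46e-07), and Aldh1a1, a retinaldehyde dehydrogenase, rose 13.3-fold (3.73 ± 0.28, adjusted p = 5.56e-05). Downward, the metalloreductase Steap4 fell by 4.49 ± 0.36 (22.4-fold, adjusted p = 7.34e-05), the neutrophil chemokine Cxcl2 fell by 3.63 ± 0.33 (12.4-fold, adjusted p = 0.000153), and the angiopoietin Angpt1 fell by 3.04 ± 0.17 (8.21-fold, adjusted p = 9.65e-06).

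Ptgdr2 rose 9.24-fold, the transmembrane mucin Muc13 5.86-fold, and Tshr, the thyrotropin receptor, 5.65-fold. Ccdc3 (6.60-fold), Cdo1, a cysteine dioxygenase (4.50-fold), Arhgef6 (3.64-fold), the potassium channel subunit Kcnab1 (3.53-fold), Cryl1 (2.78-fold), the kinase Map2k6 (2.61-fold) and the cytokine Il17d (2.45-fold) rose too. The fallers included Mmp9 (-2.31), the matricellular WNT target Ccn4 (-2.15), Ccbe1 (-2.62), the interferon-inducible GTPase Irgm1 (-1.54), the glycosyltransferase B3galt5 (-1.75) and Nfkbie (-1.17). Fam20c (-1.19), Nrep (-1.80), Itpkb (-1.10) and Fjx1 (-1.55) fell as well. These genes had an adjusted p between 9.46e-07 and 0.000153, with all 3 E2 arrays on the same side of all 3 vehicle arrays. In all, 356 probe sets rose and 464 fell, 820 of 23410, with 150 and 172 changed at least 2-fold. Esr1 (-0.45 ± 0.14, adjusted p = 0.152), Pgr (0.92 ± 0.24, adjusted p = 0.0700), Igf1 (-0.73 ± 0.20, adjusted p = 0.0780) and Ltf (0.12 ± 0.43, adjusted p = 0.969) did not pass in stroma.

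Inflammatory genes fell as a group in stroma, with 10 of 26 falling, 0 rising and 16 not passing (17 falling adjusted over the list alone). Their median was -0.70 (adjusted p = 7.77e-15, and adjusted p = 0.0847 with an estimated correlation). Besides Cxcl2, the interleukin Il1a (-3.10 ± 0.28, 8.57-fold), Cxcl5 (-2.62 ± 0.29) and Tnf (-2.58 ± 0.31) fell. Leukocyte markers, measured in the same arrays, had a median of -0.40 with 0 of 16 passing by limma, over all genes or over the list alone (adjusted p = 0.183), and their mean was 9.48 ± 0.07 (SD, n = 3) under vehicle and 9.27 ± 0.10 (SD, n = 3) under E2. Matrix proteases and inhibitors had 8 of 22 falling and 0 rising (10 and 2 adjusted over the list alone), with a median of -0.64 (adjusted p = 9.7e-07, and adjusted p = 0.0847 with an estimated correlation). They included Mmp9, Mmp14 (-0.63 ± 0.09), the plasminogen activator Plat (-1.57 ± 0.15) and the stromelysin Mmp3 (-4.23 ± 0.79, 18.8-fold, adjusted p = 0.0124). Both lists were also called by fry (adjusted p = 0.00236 each). By camera 9 of 32 lists passed, and 0 with an estimated correlation, where 0.0847 was the lowest adjusted p.

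Mitosis and G2/M genes all measured higher with E2 in stroma, 29 of 29, with a median of 0.40 (adjusted p = 1.39e-10, and adjusted p = 0.724 with an estimated correlation). Their mean per array was 7.45, 7.36 and 7.09 under vehicle and 7.54, 7.55 and 8.09 under E2, and without E2 replicate 3 the median was 0.20 (adjusted p = 0.000145). Among them the cytokinesis gene Anln alone passed by limma over all genes (1.21 ± 0.27), and 2 adjusted over the list alone. In DNA replication and G1/S the cyclin Ccne1 rose (0.37 ± 0.08) among 31, as did 1 adjusted over the list alone, and the median was 0.08 (adjusted p = 0.0301, and adjusted p = 0.724 with an estimated correlation). That call was lost without vehicle replicate 2 (adjusted p = 0.0693), vehicle replicate 3 (median 0.04, adjusted p = 0.272) or E2 replicate 3 (adjusted p = 0.229), and the median was 0.13 without vehicle replicate 1 and 0.14 without E2 replicate 1. Collagens and matrix genes had 4 of 24 falling (4 lower and 1 higher adjusted over the list alone), namely Lama1 (-1.32 ± 0.24), Col15a1 (-1.09 ± 0.20), Vcan (-1.01 ± 0.22) and Col18a1 (-0.74 ± 0.15), with a median of -0.16 (adjusted p = 0.00353, and adjusted p = 0.724 with an estimated correlation). Stromal markers had a median of -0.28 (adjusted p = 0.00353, and adjusted p = 0.724 with an estimated correlation), 0 of 20 passing by limma and 2 lower adjusted over the list alone. Heat shock genes had a median of -0.27 (adjusted p = 0.0031, and adjusted p = 0.724 with an estimated correlation), 0 of 12 passing by limma and 1 lower adjusted over the list alone, with an adjusted p of 0.0571 without vehicle replicate 2. In hypoxia and glycolysis the prolyl hydroxylase Egln3 fell (-1.49 ± 0.20) among 19, as did 1 adjusted over the list alone, with a median of -0.10 (adjusted p = 0.0301, adjusted p = 0.724 with an estimated correlation, and 0.148 without vehicle replicate 2). That median was -0.21 without vehicle replicate 1 and -0.15 without E2 replicate 3. Squamous genes had Sprr1a rising (3.25 ± 0.73) among 20, as did 1 adjusted over the list alone, with a median of 0.10 (adjusted p = 0.0451, and adjusted p = 0.724 with an estimated correlation). The squamous call was lost without vehicle replicate 2 (adjusted p = 0.0706), vehicle replicate 3 (0.0653), E2 replicate 1 (median 0.06, 0.163) or E2 replicate 2 (0.0663), and the median was 0.15 without E2 replicate 3. In the same arrays the mean of the epithelial markers was 6.96, 6.86 and 6.78 under vehicle and 7.25, 7.24 and 7.08 under E2, 15 of 19 measuring higher (median 0.10, adjusted p = 0.0806).

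**Figure D3:**
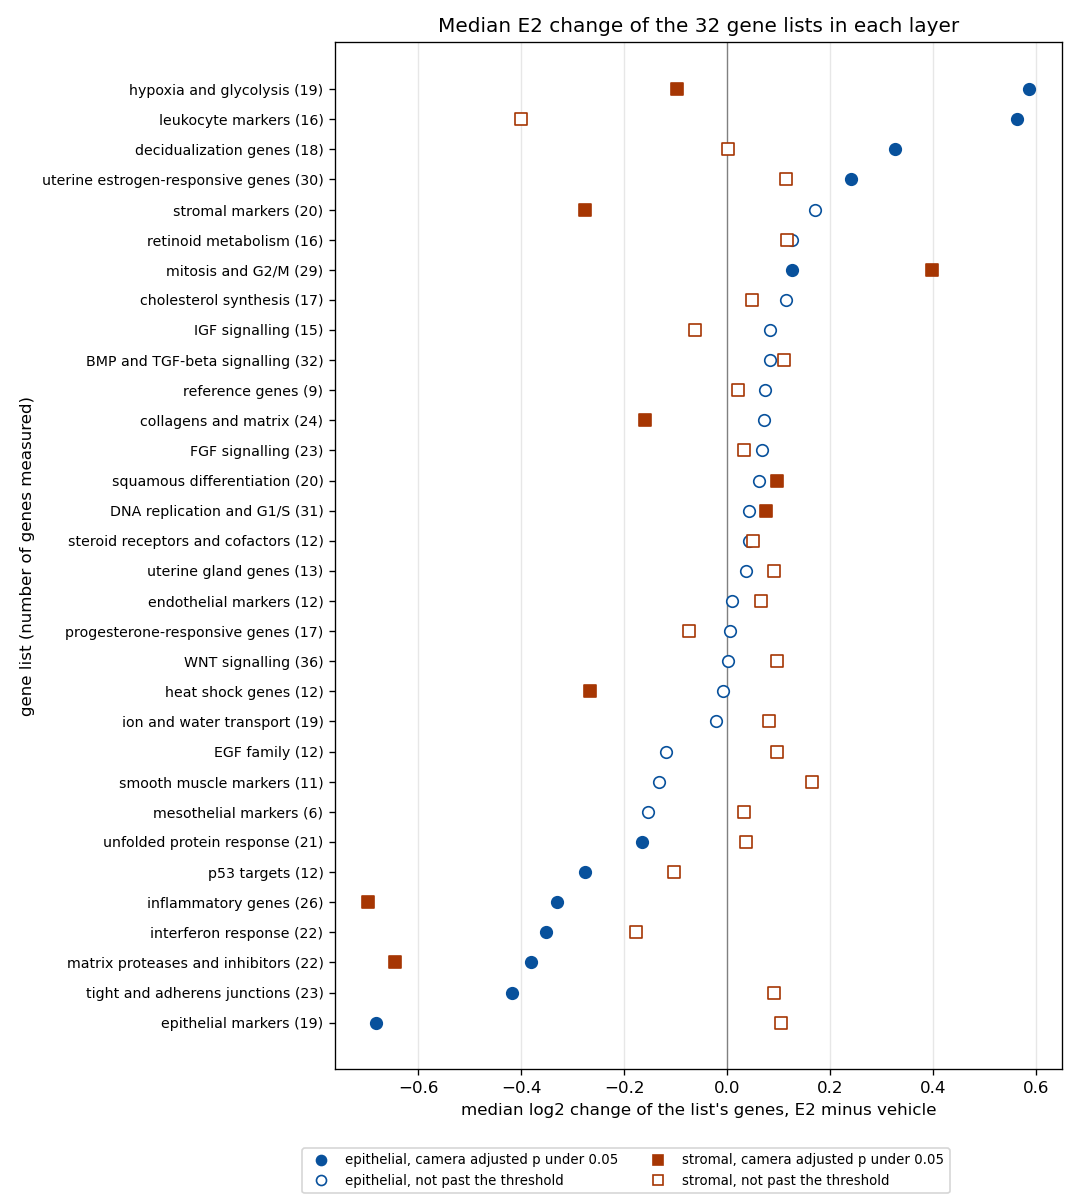
Median log2 change with E2 (horizontal axis) of each of the 32 gene lists (vertical axis, with the number of genes measured); circles are the epithelial and squares the stromal layer, filled where the camera adjusted p was under 0.05. Hypoxia and glycolysis genes stand at 0.59 in the epithelial layer, and inflammatory genes at -0.70 in the stromal layer.

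Signalling lists did not pass as groups in stroma, while single members did. In FGF signalling 2 of 23 rose, Fgf2 (0.83 ± 0.12) and Fgf12 (0.64 ± 0.08), and 5 fell, among them the keratinocyte growth factor Fgf7 (-1.83 ± 0.19, 3.55-fold) and the feedback inhibitor Spry1 (-1.58 ± 0.16), with 5 and 7 adjusted over the list alone. In the BMP list Bmp8a, the related Bmp8b (1.08 ± 0.21) and Bmp6 (0.54 ± 0.13) rose and Acvr1 (-0.50 ± 0.11) fell among 32 (4 and 2 adjusted over the list alone). In WNT signalling the receptor Fzd2 rose (0.75 ± 0.14) and the receptor Fzd1 (-1.34 ± 0.16) and the transcription factor Lef1 (-0.88 ± 0.10) fell among 36 (2 and 2 adjusted over the list alone). Igfbp4 fell (-1.46 ± 0.25) among 15 IGF genes (0 and 3 adjusted over the list alone), and Hbegf fell (-1.18 ± 0.18) and Errfi1 rose (0.65 ± 0.14) among 12 EGF family genes (1 and 1). Retinoid genes had Aldh1a1 and Crabp2 (1.61 ± 0.20) rising and Crabp1 (-2.48 ± 0.38) and Lrat (-1.63 ± 0.25) falling, 3 and 3 of 16 in all (4 and 5 adjusted over the list alone). Of 30 uterine estrogen-responsive genes, 3 rose and 2 fell (6 and 4 adjusted over the list alone), the immediate early gene Fos (1.36 ± 0.13) and Mad2l1 (0.77 ± 0.14) rising and the lipocalin Lcn2 (-1.94 ± 0.41) and Myc (-0.52 ± 0.12) falling.

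Among cell type markers in stroma, the keratin Krt7 (1.32 ± 0.28) and Cd24a (1.34 ± 0.33) rose out of 19 epithelial markers, and 3 rose adjusted over the list alone. Cnn1 (0.60 ± 0.08) and Lmod1 (0.42 ± 0.10) rose and Pcp4 (-1.07 ± 0.22) fell out of 11 smooth muscle markers (2 and 1 adjusted over the list alone). The VEGF receptor Flt1 (-1.14 ± 0.16) and Cdh5 (-1.50 ± 0.26) fell out of 12 endothelial markers, 2 adjusted over the list alone, and 0 of 6 mesothelial markers passed by limma in either count. Fkbp5 (-0.81 ± 0.15) fell out of 17 progesterone-responsive genes, Plk2 (-0.52 ± 0.11) out of 12 p53 targets and Cdh3 (-0.96 ± 0.18) out of 23 junction genes, with 1, 1 and 2 lower adjusted over the list alone. Bst2 (0.69 ± 0.15) rose out of 22 interferon genes (1 and 2 adjusted over the list alone), Aldh1a1 out of 13 uterine gland genes (1 and 0) and Bmp8a out of 18 decidualization genes (2 and 1). Steroid receptors and cofactors (12), unfolded protein response (21), cholesterol synthesis (17), ion and water transport (19) and reference genes (9) had 0 members passing by limma over all genes. Adjusted over the list alone, 1 steroid receptor gene was higher and 2 were lower, and 0 passed in the other 4 lists.

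The 820 stromal calls were 303 with E2 replicates 1 and 2 averaged, 2142 in the 6 stromal arrays alone, and 444, 471, 450, 413 and 509 without vehicle replicate 1, vehicle replicate 3, E2 replicate 1, E2 replicate 2 and E2 replicate 3. Of 71 named genes past the threshold, 47 kept their call in every fit that left out 1 array and 45 with the pair averaged, Mmp3, Krt7, Sprr1a, Anln and Bmp8b being in neither count.

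The third comparison tested whether E2 acted differently in the 2 layers, as the stromal minus the epithelial difference. It passed for 213 of 23410 probe sets, 63 higher and 150 lower in stroma. Prg4 rose by 3.59 in stroma and measured 0.49 in epithelium (difference 3.10 ± 0.21, adjusted p = 0.000243), and Muc13, Tshr and Kcnab1 followed with differences of 2.07 ± 0.19, 2.33 ± 0.23 and 2.10 ± 0.22. Nrn1 rose by 3.00 in epithelium and measured 0.02 in stroma (difference -2.98 ± 0.30, adjusted p = 0.00218). Igf1 rose by 1.16 in epithelium and measured -0.73 in stroma (difference -1.89 ± 0.28, adjusted p = 0.0111). Pgr differed by -2.06 ± 0.34 (adjusted p = 0.0186), rising by 2.98 in epithelium against 0.92 in stroma from a higher stromal starting level of 10.28 ± 0.36 (SD, n = 3). Bmp8a differed by 1.39 ± 0.28 (adjusted p = 0.0488), and Fgf10 by 0.39 ± 0.57 (adjusted p = 1), with a 95% interval of -0.86 to 1.63.

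Cxcl2 and Il1a changed by -3.63 and -3.10 in stroma and measured -0.20 and -0.83 in epithelium, differences of -3.43 ± 0.47 and -2.27 ± 0.40. Fgf7 and Egln3 changed by -1.83 and -1.49 in stroma and measured 0.54 and 0.34 in epithelium, differences of -2.36 ± 0.27 and -1.84 ± 0.28. Of the lists, 14 of 32 passed by camera, and 0 passed with an estimated correlation (lowest adjusted p = 0.358) or by fry. Hypoxia and glycolysis had the smallest p among them, with 19 of 19 members lower in stroma than in epithelium in their response and a median of -0.63 (adjusted p = 5.24e-15, and adjusted p = 0.358 with an estimated correlation). Epithelial markers differed by 1.00 (adjusted p = 3.73e-10, and adjusted p = 0.582 with an estimated correlation). The number of calls was 12 with E2 replicates 1 and 2 averaged and 128 when every probe set of the table was tested. Leaving out 1 epithelial array gave 127 (vehicle replicate 1), 725 (vehicle replicate 3), 97 (E2 replicate 1), 83 (E2 replicate 2) and 712 (E2 replicate 3), and leaving out 1 stromal array gave 120 (vehicle replicate 1), 103 (vehicle replicate 3), 84 (E2 replicate 1), 81 (E2 replicate 2) and 129 (E2 replicate 3). The balance of directions moved too, with 326 higher and 399 lower without epithelial vehicle replicate 3 and 115 and 597 without epithelial E2 replicate 3.

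**Figure D4:**
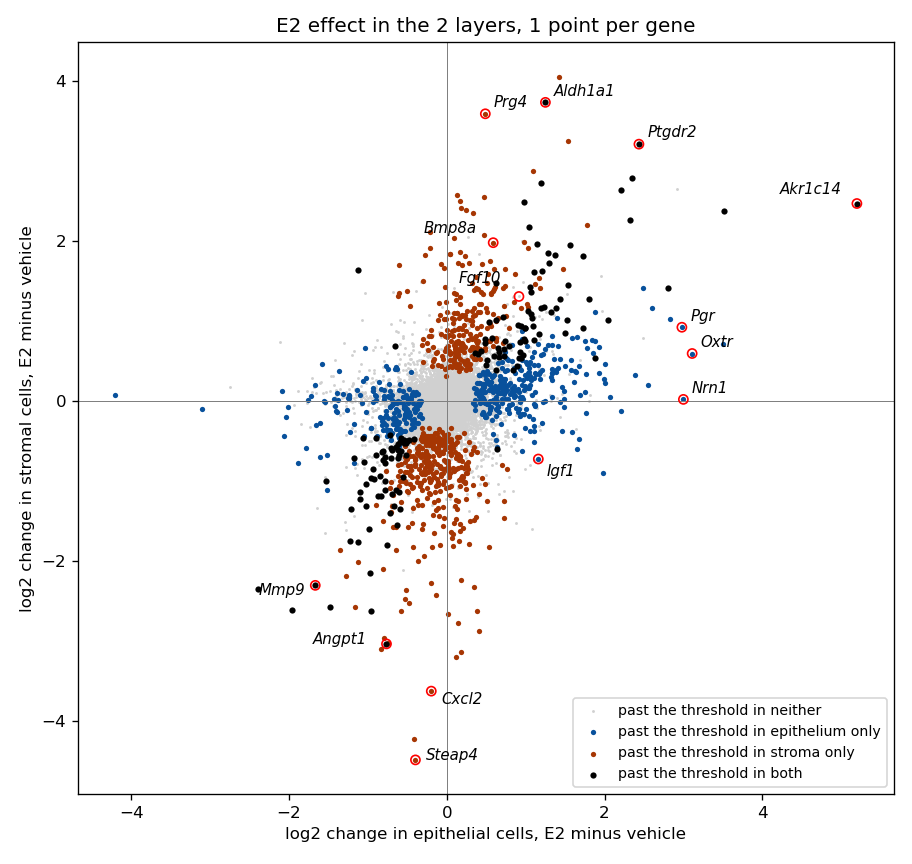
Log2 change with E2 in epithelial cells (horizontal axis) against stromal cells (vertical axis) for 19938 genes, 1 point per gene, coloured by the layer in which the gene passed the threshold; ringed genes are named. Both layers share 73 genes that rose and 62 that fell, and 3 genes changed in opposite directions.

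Across probe sets the log2 changes of the 2 layers correlated with Pearson r = 0.32 and Spearman rho = 0.31, where probe sets are not independent replicates. Higher in both layers were 76 probe sets, against 6.31 expected for independent lists, and lower in both were 69, against 5.21. Higher in epithelium and lower in stroma were 10, against 8.23, and the reverse held for 2, against 4.00. These expectations take the layers as independent, although vehicle arrays of the same number correlated at 0.17, 0.14 and 0.13 between the layers. The epithelial arrays also measured stromal markers, with list means of 10.67 under vehicle and 10.97 under E2, against 11.52 and 11.29 in stroma. Whether stromal cells in the inserts made part of the overlap was not tested. Ptgdr2, Akr1c14 and Glul rose in both layers, and Mmp9, Mmp14, Nfkbie, Fam20c and Cxcl5 fell in both.

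The fourth comparison asked how the layers differed under vehicle. Epithelial genes marked the epithelial layer, with the junction adhesion molecule F11r 24.8-fold higher (4.63 ± 0.16, adjusted p = 1.63e-07), the keratin Krt8 24.2-fold (4.60 ± 0.19), Cldn4 36.8-fold (5.20 ± 0.25) and the mucin Muc1 42.9-fold (5.42 ± 0.33). The secreted proteins Ltf (5.51 ± 0.43) and Clu (31.2-fold, 4.96 ± 0.19) and the squamous gene Sprr2f (57.9-fold, 5.85 ± 0.27) were also higher in epithelium. Stroma was higher in the fatty acid carrier Fabp4 (-3.94 ± 0.17), the retinol carrier Rbp4 (-4.49 ± 0.36), the WNT antagonist Dkk2 (-3.66 ± 0.24), Cxcl2 (-3.62 ± 0.33) and the repressor Prdm1 (-3.50 ± 0.21). Pgr (-2.69 ± 0.24), Esr1 (-0.86 ± 0.14), Igf1 (-1.09 ± 0.20) and Bmp8a (-0.89 ± 0.20) were higher in stroma too, while Fgf10 measured 1.08 ± 0.40 higher in epithelium and did not pass (adjusted p = 0.0809). In all 1703 probe sets were higher in epithelium and 3298 in stroma, 5001 of 23410, with 608 and 698 at least 2-fold and 192 and 124 at least 4-fold apart. Both counts depended on the scaling, since centring each array on its median gave 1118 and 5266 and moved the median difference of all probe sets from 0.02 to -0.12.

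Epithelial markers passed in 18 of 19 genes under vehicle, all higher in epithelium (19 adjusted over the list alone, median 3.69), and mesothelial markers in 6 of 6 (median 3.04), with Msln 18.3-fold and Upk1b 15.6-fold higher in the epithelial layer. Smooth muscle markers were lower there in 10 of 11 (11 adjusted over the list alone, median -0.89), such as Lmod1 (-1.21 ± 0.10) and Myh11 (-1.63 ± 0.22). Stromal markers were lower in 11 of 20 (11 lower and 1 higher adjusted over the list alone, median -0.80), such as Zeb1 (-1.83 ± 0.15), Hoxa11 (-2.01 ± 0.28) and Twist2 (-2.83 ± 0.41). Leukocyte markers were lower in 11 and higher in 1 of 16 (12 and 1 adjusted over the list alone, median -1.28), such as Csf1r (-1.98 ± 0.14) and C1qc (-1.57 ± 0.15). Hypoxia and glycolysis genes were lower in 11 and higher in 1 of 19 (16 and 1 adjusted over the list alone, median -0.57), such as Adm (-1.76 ± 0.19), and junction genes were higher in 13 and lower in 1 of 23 (15 and 2 adjusted over the list alone, median 0.89). By camera 13 of 32 lists passed (adjusted p from 4.92e-20 to 0.0483), 12 of them also by fry, and 0 passed with an estimated correlation (lowest adjusted p = 0.0819).

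The fifth comparison repeated this under E2, where 1036 probe sets were higher in epithelium and 2148 in stroma (757 and 3258 with each array centred on its median), and 166 and 85 at least 4-fold apart. Sprr2f (61.5-fold, 5.94 ± 0.27), F11r (15.7-fold, 3.97 ± 0.16), Krt8 (17.8-fold, 4.15 ± 0.19) and the sodium pump subunit Atp1b1 (17.1-fold, 4.10 ± 0.21) were higher in epithelium. Prg4 (-2.94 ± 0.15), Tshr (-2.90 ± 0.16), Cdo1 (-3.15 ± 0.19), the endothelial co-receptor Eng (-2.74 ± 0.17) and Muc13 (-2.14 ± 0.13) were higher in stroma. Bmp8a (-2.28 ± 0.20, adjusted p = 3.31e-05) and Bmp8b (-1.78 ± 0.21) were higher in stroma, Fgf9 (2.43 ± 0.22), Fgf7 (1.81 ± 0.19) and Igf1 (0.80 ± 0.20, adjusted p = 0.0192) in epithelium. Fgf10 (0.69 ± 0.40, adjusted p = 0.293), Pgr (-0.63 ± 0.24, adjusted p = 0.121) and Esr1 (-0.16 ± 0.14, adjusted p = 0.506) did not pass. Epithelial markers were higher in 13 of 19 (16 adjusted over the list alone, median 2.06), mesothelial markers in 6 of 6 (median 2.98), and inflammatory genes in 8, with 2 lower, of 26 (9 and 2 adjusted over the list alone, median 0.42), among them Il1a (3.73 ± 0.28) and Lcn2 (4.42 ± 0.41). Smooth muscle markers were lower in 10 of 11, over all genes or over the list alone (median -0.95), such as Actg2 (-2.88 ± 0.21). By camera 11 of 32 lists passed (adjusted p from 4.32e-15 to 0.0330), 9 of them also by fry, and 0 passed with an estimated correlation (lowest adjusted p = 0.0504). The 3184 calls were 1420 with E2 replicates 1 and 2 averaged, and 2110 and 1953 without stromal E2 replicate 1 and stromal E2 replicate 2.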

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

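The tests chosen only after the result was seen were those of the leukocyte and smooth muscle markers, of the smooth muscle median, of the leukocyte markers and the matched random lists in stroma, of the closeness of E2 replicates 1 and 2, of the averages of E2 replicates 1 and 2 and of other pairs, of the lists without each array, of every set of 10 splits, and of the covariates. The 100 joint splits, the count above the stromal level and the median of all probe sets had their tests set before those results were seen.

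A test of the difference itself singled out the genes whose E2 response differed between the layers, 213 of 23410 probe sets. Values are the stromal minus the epithelial log2 difference. The difference was positive for Prg4, the lubricin gene (3.10, adjusted p = 0.000243), Muc13 (2.07), Tshr (2.33), the fibulin Fbln5 (1.33), the matrix protein Adamtsl1 (2.76) and the cytokine Il17d (1.13). It was also positive for Kcnab1 (2.10), Arhgef6 (1.70), Slc35f2 (1.15), the synaptotagmin Syt1 (2.44), the palmitoyltransferase Zdhhc2 (1.21) and Fam124a (0.91). The difference was negative for Fgf7 (-2.36), Igf1 (-1.89), Angpt1 (-2.27), Cxcl2 (-3.43), Il1a (-2.27), the NF-kappaB inhibitor Nfkbia (-1.41) and Igfbp4 (-1.83). It was also negative for Idh1 (-1.34), which measured 1.88 in epithelium and 0.54 in stroma, and for B3galt5 (-1.91), Itpkb (-1.35), Egln3 (-1.84), Lrat (-1.79), Plat (-1.08) and the cation channel Trpc6 (-2.88). Nrn1 (-2.98), Tlnrd1 (-1.98), Doc2b (-1.57), Amtn (-1.61), Lrrc15 (-3.28), Kap (-1.65), Pgr (-2.06), Lef1 (-0.90), Sfrp4 (-2.16) and Gja1 (-1.24) were negative too. The keratin Krt7 (1.93), the calponin Cnn1 (0.73), Msln (1.40), Fos (0.93), Bmp8a (1.39, adjusted p = 0.0488) and Aldh1a1 (2.48) had positive differences. Of the 42 genes so named, 27 passed in each of the 12 fits that left out 1 array and 11 passed with E2 replicates 1 and 2 averaged. Prg4, Muc13, Tshr, Nrn1 and Kap were in both counts, whereas Bmp8a passed in 3 of the 12 fits, Pgr in 7 and Krt7 and Fos in 2 each.

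Gene lists whose response differed by the same kind of test were hypoxia and glycolysis (median -0.63, adjusted p = 5.24e-15), epithelial markers (1.00), leukocyte markers (-0.70), stromal markers (-0.40), inflammatory genes (-0.49), mitosis and G2/M (0.24), unfolded protein response (0.22), smooth muscle markers (0.33), collagens and matrix (-0.24), tight and adherens junctions (0.30), heat shock genes (-0.25), uterine gland genes (0.14), interferon response (0.20) and FGF signalling (-0.175). With an estimated correlation none passed, with adjusted p = 0.358 for hypoxia and glycolysis, 0.598 for collagens and matrix, 0.61 for mitosis and for interferon, and 0.582 for the other 10. The first 5 lists passed without each array in turn. Without epithelial vehicle replicate 2 the adjusted p was 0.361 for junctions, 0.0944 for the unfolded protein response, 0.164 for mitosis, 0.147 for collagens, 0.148 for FGF signalling, 0.311 for interferon, 0.0838 for heat shock and 0.12 for gland genes. Without epithelial vehicle replicate 3 it was 0.0637 for smooth muscle markers, 0.145 for interferon and 0.191 for heat shock, and without epithelial vehicle replicate 1 it was 0.0522 for FGF signalling, collagens and gland genes. Without epithelial E2 replicate 1 it was 0.0506 for interferon, 0.0723 for heat shock and 0.0999 for gland genes. Without epithelial E2 replicate 2 it was 0.0688 and 0.0589 for interferon and gland genes, and without epithelial E2 replicate 3 it was 0.109 and 0.0549 for FGF signalling and collagens. Without stromal vehicle replicate 2 it was 0.479, 0.14 and 0.129 for interferon, heat shock and gland genes, and without stromal vehicle replicate 3 it was 0.0572 and 0.0727 for FGF signalling and mitosis. Without stromal E2 replicate 3 it was 0.0592, 0.317 and 0.13 for FGF signalling, mitosis and interferon.

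Other splits of the same arrays were run beside each count. For E2 in epithelium 2 of the 10 splits of the 6 arrays into 3 and 3 gave at least as many calls as the 678 of the real split, the highest other giving 3448. For E2 in stroma it was 1 of 10 (real 820, highest other 1), for the layers under vehicle 1 of 10 (real 5001, highest other 0), and for the layers under E2 1 of 10 (real 3184, highest other 0). The 10 splits are too few for a share under 0.05. Each other split also mixes the 2 sides within its groups, which puts their difference into the spread. Few calls in the other splits, above all between the layers, were therefore built in. For the difference of the responses, 3 of 100 joint splits gave at least 213 calls, the highest other giving 1610. Such splits also break up any E2 effect common to the layers, which adds to the spread and lowers their calls. They address whether E2 had no effect in either layer, so they cannot exclude chance for the difference. They also take the arrays of the layers as independent of each other. With arrays of the same treatment and number moved together it was 1 of 10 (real 213, highest other 1), again too few splits for a share under 0.05, and neither count allows for the closeness of E2 replicates 1 and 2. The epithelial split with 3448 calls set vehicle replicate 2 and E2 replicates 1 and 2 against vehicle replicates 1 and 3 and E2 replicate 3, and it points to a structure of the samples other than treatment. In it 1295 probe sets were higher and 2153 lower, 6 of them also called for E2. The array medians over all probe sets of the table were 7.07, 7.01 and 7.01 on the first side and 7.11, 7.08 and 7.14 on the other. All 413 of 1027 olfactory receptor genes that passed were lower, 7 of 17 cholesterol synthesis genes were higher, and the median difference went from -0.18 in the lowest 25% of probe sets by mean value to 0.14 in the highest 25%. With this split as a covariate, chosen for its count, the E2 calls in epithelium were 4510 and included all 678. No biological explanation of this split was tested.

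In the epithelial layer epithelial and junction genes measured lower with E2, leukocyte markers such as Csf1r higher, and 415 probe sets rose. A lower share of epithelial cells would raise the markers of other types alike only under certain conditions. The other types would have to keep their proportions, with markers found in them alone and not changed by E2 itself. Leukocyte and smooth muscle markers moved apart by 0.67. The leukocyte minus smooth muscle mean was -1.42, -1.51 and -1.40 under vehicle and -0.68, -0.43 and -1.21 under E2. Those conditions were not tested, and the smooth muscle gene Actg2 passed as a faller (-1.02). The difference therefore cannot decide on a lower epithelial share, which stays open. More stromal cells like those on the cover slips cannot lift a gene above its level in stroma. Of the 415 probe sets that rose, 131 (31.6%) ended above the E2 stromal level past the threshold. Whether stromal cells in the inserts had that level was not tested, and both comparisons used the same E2 epithelial arrays. The 131 therefore do not exclude a larger share of other stromal cells. Of the other 284 that rose, 212 started lower in epithelium than in stroma under vehicle. For the 284 a response of epithelial cells and a larger stromal share cannot be told apart. The median of the smooth muscle markers was -0.13, with list means of 9.94, 9.71 and 9.95 under vehicle and 9.83, 9.65 and 9.65 under E2. Stromal marker means were 10.60, 10.29 and 11.12 under vehicle and 10.99, 11.01 and 10.91 under E2. Both lists overlapped between the treatments, so neither decides. Akr1c14, Pgr and Ptgdr2, which measured lower in epithelium than in stroma under E2, were among these 284. With the epithelial marker mean as a covariate 306 probe sets passed, 210 of them among the 678. An epithelial response to E2 stays open for those 131, as does a change in the leukocytes themselves for their markers, and neither was tested; arrays of sorted epithelial cells would decide the first.

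In stroma 10 of 26 inflammatory genes fell, with a median of -2.26 among those 10, Il1a, Cxcl2, Cxcl5 and Tnf included. Over all 26 genes the median was -0.70, and the mean per array was 9.58, 8.96 and 9.62 under vehicle and 8.31, 8.35 and 8.22 under E2. Leukocyte markers had a median of -0.40, and their mean moved by -0.21 (95% interval -0.41 to -0.00361), with 0 of 16 passing by limma. If an even loss of all leukocytes were the whole cause, the 26 genes and the markers would fall alike. The mean of the 26 genes minus that of the markers changed by -0.89 (95% interval -1.37 to -0.41), which argues against such an even loss. Both intervals count E2 replicates 1 and 2 as separate samples, although these lay close together and may not be. Loss of only some leukocytes, which the marker mean need not follow, was not tested as the whole cause. A part played by fewer leukocytes stays open. A shift of the E2 arrays shared by genes of the same level is argued against by 10000 random lists matched on mean value, whose lowest median was -0.19. The median of all probe sets, 0.0264, was the first test set for a general shift, but the normalization holds it near 0. A response of the cells to E2 may be a candidate explanation, found and tested on the same data.

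E2 replicates 1 and 2 lay close together in both layers. The SD of their difference was 0.165 in epithelium and 0.113 in stroma, against 0.273 to 0.529 and 0.178 to 0.248 for the other pairs within a group. The ratio of the pair to the closest other pair was 0.633 in stroma and 0.602 in epithelium, which is consistent with 1 co-culture or RNA pool measured more than once. The labels do not say so, and 2 cultures that happened to be alike stay open. With the pair averaged 37.0% of the stromal and 13.1% of the epithelial number of calls was left. Averaging also takes away an array per layer, so each other pair of replicates was averaged in the same way. The lowest count was then 389 in epithelium, against 89 for this pair, and 520 in stroma, against 303. Averaging the closest pair takes away the least spread between arrays, so a lower count is built into the choice of this pair. The counts therefore do not separate the loss of an array from the closeness of the pair. Without epithelial E2 replicate 3, which keeps the pair, 1513 passed in epithelium, and without E2 replicate 1 or E2 replicate 2 it was 219 and 220. In stroma the numbers were 509 without E2 replicate 3, 450 without E2 replicate 1 and 413 without E2 replicate 2, beside 444 and 471 without vehicle replicate 1 and vehicle replicate 3, so that leaving out single arrays does not set the pair apart there. No biological explanation was tested.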

How the results depend on the processing

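Chosen after seeing the data were the tests with E2 replicates 1 and 2 averaged, with the epithelial marker mean and with the split of the epithelial arrays as covariates, and the gene list tests without each array; the other alternatives were planned.

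Of 8950 values of named genes under an alternative, 8044 stayed on the same side of the threshold, 881 kept direction but lost the threshold and 25 gained it. In 0 of them the direction reversed where either fit passed. Changes of direction where neither fit passed were not counted apart, so the 8044 can include them. The counts that moved by over 1.5 times were these, in the order of the report. Testing all probe sets of the table gave 128 for the difference of the responses. Quantile normalization once more gave 1044 for E2 in epithelium. Array weights, which gave E2 replicate 2 of each layer a weight of 6.01 (epithelium) and 6.69 (stroma), gave 4706, 4503, 4488, 9867 and 11798. An adjusted p under 0.10 gave 1289 for E2 in epithelium and 404 for the difference, by its looser threshold. Requiring 1.5-fold gave 2870 and 2009 for the layers under vehicle and E2, and requiring 4-fold gave 316 and 251, by their stricter threshold.

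The 6 arrays of the layer alone gave 49 in epithelium, 47 of them among the 678, and 2142 in stroma, 815 of them among the 820. The epithelial arrays spread more, and the fit of 12 arrays shares 1 variance. A replicate block within each layer gave 438 in epithelium and 126 for the difference. With E2 replicates 1 and 2 averaged, 89 (epithelium), 303 (stroma), 12 (difference) and 1420 (layers under E2) passed. The marker covariate gave 306 in epithelium. The split covariate gave 4510, 1471 and 763 for epithelium, stroma and the difference (396 higher and 367 lower). Unless named here, the cause was not tested.

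Leaving out 1 array in turn gave 219 to 1634 in epithelium, 413 to 664 in stroma, 81 to 725 for the difference and 1953 to 2929 for the layers under E2. The extremes were without epithelial E2 replicate 1 and vehicle replicate 3, stromal E2 replicate 2 and vehicle replicate 2, stromal E2 replicate 2 and epithelial vehicle replicate 3, and stromal E2 replicate 2 and epithelial E2 replicate 1. For the layers under vehicle it was 3385 to 7197 against 5001.

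Of the gene lists, 0 passed with an estimated correlation in each of the 5 comparisons, while fry called 3 in epithelium, 2 in stroma and 0 for the difference. With the marker covariate 16 passed in epithelium, 9 of the 12 among them, but not epithelial markers (adjusted p = 0.693, where the covariate is their own mean), junctions (0.694, direction reversed) or the unfolded protein response (0.0644). Beyond 95% of random lists lay 15 in stroma against 9 by camera, 6 of them shared; DNA replication and G1/S, hypoxia and glycolysis, and squamous genes were not among them (percentiles 96.4, 3.11 and 97.3). Leaving out 1 array gave 7 to 17 lists for the difference, against 14. The correlation of the 2 layers was 0.34 without the lowest 40% of probe sets, against 0.32. Centring each array on its median moved the share of probe sets higher in epithelium from 34.1% to 17.5% under vehicle and from 32.5% to 18.9% under E2.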

Other observations

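The genes named here were chosen after their values were seen, as members of the 73 genes that rose and the 62 that fell in both layers. Changes are log2 differences with E2, the epithelial value first, with n = 3 arrays per group. Among those that rose in both layers were Dio2, the deiodinase that activates thyroid hormone (2.32 ± 0.49 and 2.26 ± 0.49), Lgr6, an R-spondin receptor (2.21 ± 0.49 and 2.63 ± 0.49), the sphingosine phosphate receptor S1pr1 (1.37 ± 0.22 and 1.83 ± 0.22) and Vegfd, a lymphatic growth factor (1.56 ± 0.35 and 1.95 ± 0.35). Tagap (2.35 ± 0.29 and 2.78 ± 0.29), the ADP-ribosyltransferase Tiparp (1.54 ± 0.24 and 1.45 ± 0.24), the homeobox gene Irx1 (1.08 ± 0.14 and 1.03 ± 0.14), the small GTPase Rras2 (1.00 ± 0.11 and 0.90 ± 0.11) and the serine protease Htra3 (1.44 ± 0.22 and 1.27 ± 0.22) rose as well.

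Among the genes that fell in both layers were the platelet chemokine Ppbp (-2.39 ± 0.50 and -2.35 ± 0.50), Cx3cl1 (-1.22 ± 0.22 and -1.75 ± 0.22) and the netrin Ntn1 (-1.12 ± 0.17 and -1.77 ± 0.17). The retinol transporter Stra6 (-1.10 ± 0.26 and -1.22 ± 0.26), the NADPH oxidase Nox4 (-0.88 ± 0.16 and -1.19 ± 0.16) and the cytokine signalling inhibitor Cish (-0.71 ± 0.11 and -0.71 ± 0.11) fell too. The TGF-beta receptor Tgfbr1 fell by 0.94 ± 0.09 and 0.86 ± 0.09.

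The 3 genes past the threshold in opposite directions were also picked after their values were seen. The microtubule end gene Mapre2 rose in epithelium and fell in stroma (0.64 ± 0.11 and -0.60 ± 0.11, adjusted p of the difference = 0.00527). The elastic fibre gene Fbln5 (-0.65 ± 0.12 and 0.68 ± 0.12, adjusted p of the difference = 0.00691) and Adamtsl1 (-1.12 ± 0.22 and 1.64 ± 0.22, adjusted p of the difference = 0.00333) went the other way. Akr1c14 rose in both layers, by 5.20 in epithelium and 2.47 in stroma (adjusted p of the difference = 0.013).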
